A study of Mus musculus with 6 samples.

How the data were processed

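Total RNA from the hippocampus of 12-month-old C57BL/6 mice was extracted with Trizol and made into strand-specific libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. Reads were aligned with TopHat to mm10, per the submitters' processing notes. The TopHat version, the gene annotation, and the program that turned alignments into abundances are not given in the sources used here. There was 1 deposited table per library with 24346 gene symbols and 1 value each.

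The deposited values are on a log2 scale, and this was read from the values because no header or label names the unit. They were never negative, and 2 to the power of the value, minus 1, behaved as FPKM (fragments per kilobase of transcript, scaled by the depth of the library): the sum over protein-coding genes differed between libraries (346423 to 368441), and low values divided into steps that depended on gene length. Of genes under 3.5 steps, 75.0% to 78.0% per library lay within 0.15 of a whole step. The step size corresponded to about 10900000, 8880000 and 9850000 fragments in WT 1 to WT 3 and to 8150000, 9000000 and 12900000 in HET 1 to HET 3, which is an estimate and not a deposited count. Where the unit alone is wrong, the FPKM values and ratios change and the log2 differences of single genes do not. The filter of 1 FPKM rests on the same reading, and with it the set of genes tested and the adjusted p-values. So does the value given below for a loss of 50% of Nfat5. With another log base the log2 differences would change as well. In 4 libraries (WT 1, WT 3, HET 1 and HET 3), 2199 to 2609 genes had tiny values under 0.001 FPKM in place of 0, and 4262 genes were at 0 in all 6 libraries. Sorted values differed between libraries, so the values had not been quantile-normalized.

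Groups followed the labels: 3 wild-type and 3 TonEBP+/- libraries. Genes at 1 FPKM or more in at least 3 libraries were kept (13122). Their deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit with genotype as the only term, eBayes with trend and robust options), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Because the scale is log2(value + 1), differences of genes with low values are understated. The design had foreseen a form for each unit, and that for log values applied. Single genes were also compared with a two-sided exact permutation test where stated. Unless another test is named, an adjusted p of a gene is from limma and that of a list from camera.

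Before the data were examined, 38 gene lists (pathways, cell types, regions, RNA quality, and the neighbours of Nfat5) were fixed, along with the design and most alternatives. The 37 lists with tested members were compared with camera at a preset correlation of 0.01, adjusted over the 37. The remaining list, of mitochondrially encoded transcripts, was not analysed here. Camera with an estimated correlation and fry were alternatives. The genes to name were set by rule: Nfat5 and Trim37; up to 12 genes per direction past the threshold with no overlap between genotypes; where fewer passed, the 6 with the smallest p per direction, stated as not passing, without unnamed models, pseudogenes and small RNAs; the 2 to 4 members with the smallest p in each list described, of which a few are not reported here; and flanking genes past the threshold. Positions are from the NCBI gene table of GRCm38, the assembly that mm10 names, matched by symbol for 13091 of the 13122 genes.

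The procedure was tested on simulated data made from the means and spreads of the 13122 genes in these 6 libraries. With 200 genes changed per draw and 20 draws, changes of 0.3, 0.5, 0.75 and 1 on the log2 scale were recovered at 15.8%, 68.6%, 90.3% and 96.6%, and 7.28% of the calls were false on average, somewhat above the nominal 5%. With camera, 1 list of 20 independent genes shifted by 0.1 among 37 lists was found in 85.0% of the draws, with 0 false lists on average. Real lists hold correlated genes, which this simulation does not include.

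Alternatives were quantile normalization, median scaling, no filter, a stricter filter (mean of at least 5 FPKM), no robust option, a pseudocount of 0.1, a replicate block, each library left out in turn, an adjusted p of 0.1, and neighbours of Nfat5 taken from the annotation. A covariate for thalamus markers was added after seeing the data. Alternatives planned for counts (library size factors, voom, and count models) did not apply to these values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.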

Results

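Hippocampal RNA was profiled in 6 libraries from 12-month-old C57BL/6 mice, 3 from wild-type animals and 3 from littermates carrying 1 disrupted allele of the gene for TonEBP (TonEBP+/-). TonEBP, the tonicity-responsive enhancer binding protein, is a transcription factor of the NFAT family encoded by Nfat5. Each file listed 24346 gene symbols with log2(value + 1) of an abundance that behaved as FPKM, a value scaled by transcript length and library depth. The values below are given in FPKM on that reading of the files. The number of fragments was not listed. The step between low values corresponded to about 8150000 (HET 1) to 12900000 (HET 3) fragments per library, so that 1 fragment in a transcript of 1 kb was worth 0.0773 to 0.123 FPKM. The labels number the mice 1 to 3 in each genotype (WT 1 to WT 3, HET 1 to HET 3) and say no more on how they were kept apart. The p-values of single genes therefore measure the spread between these samples. Those of lists in camera at the preset correlation of 0.01 set genes of a list against other genes. Those of Fisher's exact test count genes. Neither of these 2 kinds measures the spread between mice.

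The first comparison asked whether the disrupted gene, and the gene named in the title of the series, differed between genotypes. Nfat5 (chromosome 8, 107293435 to 107379517, GRCm38) was at 9.53 ± 1.07 FPKM (SD, n = 3) in wild-type libraries and at 8.66 ± 0.567 FPKM (SD, n = 3) in libraries labelled TonEBP+/-. The single libraries were at 10.5, 8.39 and 9.72 FPKM in wild type and at 8.25, 9.31 and 8.42 FPKM in the libraries labelled TonEBP+/-, and the ranges overlapped. The log2 change was -0.12 (SE 0.0963, 95% interval -0.34 to 0.09, limma adjusted p = 1.00), and the two-sided exact permutation test gave p = 0.3. A loss of 50% of the transcript would be a change of -0.87 on this scale, which lay outside the interval. The labels do not say which part of the gene was disrupted, and transcripts of a disrupted allele can still be counted in a whole-gene value. The value therefore did not check the labels, and the directions below are those of the libraries as labelled. Trim37 (chromosome 11, 87126790 to 87250874), which encodes a ubiquitin ligase of the tripartite motif family, was at 93.0 ± 0.622 FPKM (SD, n = 3) in wild type and 89.6 ± 1.44 FPKM (SD, n = 3) in libraries labelled TonEBP+/-, a ratio of 0.963. All 3 libraries labelled TonEBP+/- were below all 3 wild-type libraries, for which the exact permutation test gave p = 0.1, the smallest that 3 against 3 allow. The log2 change of -0.05 (SE 0.0609, 95% interval -0.19 to 0.08) did not pass the limma test (adjusted p = 1.00, and 0.398 adjusted over the pair Nfat5 and Trim37 alone).

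**Figure D1:**
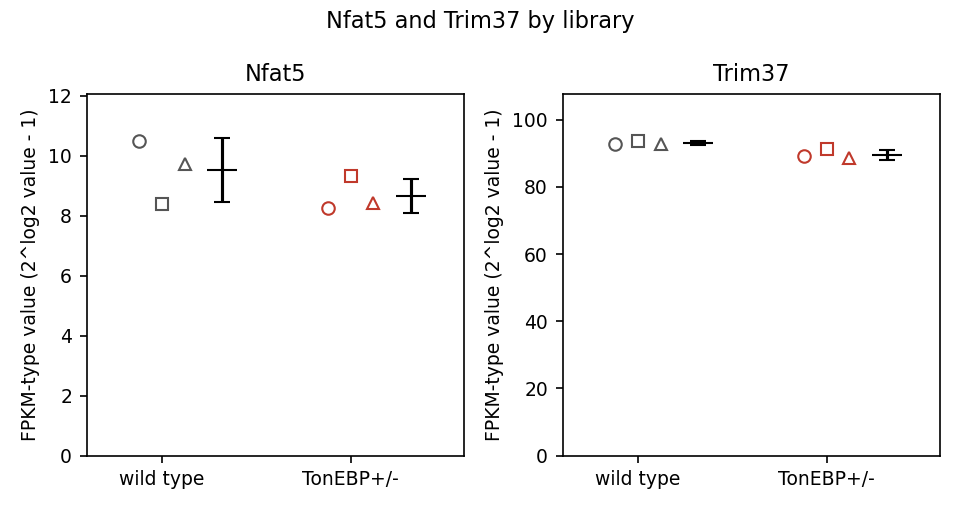
FPKM-type values of Nfat5 (left) and Trim37 (right) on linear axes that start at 0, with one open symbol per library and, to the right of each group, a bar at the mean with its SD (n = 3). Nfat5 ranged from 8.25 to 10.5 FPKM with overlap between genotypes, and Trim37 from 88.5 to 93.7 FPKM without overlap.

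Across the transcriptome, the question was which hippocampal genes differ between the genotypes. Of 13122 genes tested, 0 passed an adjusted p of 0.05 in limma, 484 had an unadjusted p under 0.05 (243 higher and 241 lower in libraries labelled TonEBP+/-), and chance gives 656.1. The smallest adjusted p was 0.383. The 2 genotypes did not overlap in 1118 genes, 8.52% of those tested, where chance gives 10%. The median SE of a log2 change was 0.0991. Simulated changes of 0.5, 0.75 and 1 on the log2 scale in this comparison were recovered at 68.6%, 90.3% and 96.6%, and those of 0.3 at 15.8%. These rates hold for 200 genes changed per draw, with noise that was independent between genes. They do not give the rate for a change in only a few genes, where the adjustment over all genes is harder to pass.

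The genes with the smallest p are described here although none passed. Rims1, which encodes a scaffold protein of the presynaptic active zone, was at 70.8 ± 10.2 FPKM in wild type and 114 ± 5.72 FPKM in libraries labelled TonEBP+/- (SD, n = 3 each), a log2 difference of 0.69 (SE 0.0988, adjusted p = 0.383). A pair of histone genes, Hist1h2ad (log2 difference 1.06, SE 0.157, adjusted p = 0.383) and Hist1h2bk (0.92, SE 0.187, adjusted p = 0.945), lay higher at low levels, with 1.57 and 0.701 FPKM in wild type against 4.28 and 2.15 FPKM. Histone genes have near-identical copies, and how reads shared between them were assigned is not given in the sources used here. These values are therefore uncertain. Hist1h2bk (chromosome 13, 22035821 to 22036320) is shorter than 1 kb, so 1 fragment in it was worth more than the 0.0773 to 0.123 FPKM given above. Its values of 0.538, 0.341 and 1.22 FPKM in WT 1 to WT 3 can rest on few fragments. Crip1, a LIM domain protein gene, had a log2 difference of 0.41 (SE 0.0954), Cxcr4, a chemokine receptor gene, of 0.53 (SE 0.124), and Ccdc107 of 0.35 (SE 0.0837), each with an adjusted p of 1.00. Among lower values were those of Scn4b, a sodium channel subunit gene (11.0 ± 0.155 against 6.82 ± 1.28 FPKM, log2 difference -0.63, SE 0.112, adjusted p = 0.872), and Unc13c, a gene for a vesicle priming protein (21.6 ± 1.92 against 14.7 ± 1.53 FPKM, log2 difference -0.53, SE 0.0953, adjusted p = 0.872; SD, n = 3 each). Vamp1, a synaptobrevin gene, was at 63.3 ± 0.526 FPKM in wild type and 45.4 ± 6.93 FPKM in libraries labelled TonEBP+/- (SD, n = 3 each; log2 difference -0.48, SE 0.0987). The early response gene Btg2 had a log2 difference of -0.59 (SE 0.115), Arhgap24, which encodes a GTPase-activating protein, of -0.58 (SE 0.116), and Apold1, an early response gene of endothelium, of -0.67 (SE 0.138), and these 4 genes shared an adjusted p of 0.945. In all 12 genes the 3 libraries of one genotype lay apart from the 3 of the other.

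The count of 0 depended on single libraries. Without HET 1, 8 genes passed, all lower in libraries labelled TonEBP+/-: Slc17a6, Prkcd, Scn4b, Plcb4, Adarb1, Shox2, Inadl and Plekhg1. HET 2 and HET 3 were low in thalamus markers, as given below, and 2 of the 8 genes (Prkcd and Plekhg1) belong to that list. Thalamic neurons express Slc17a6 too, and the log2 difference of Scn4b was smaller with the thalamus covariate (-0.44 in place of -0.63). Whether Plcb4, Adarb1, Shox2 and Inadl follow the thalamic content was not tested. Without WT 1, WT 2 or HET 3, 1 gene passed in each case, which was Snord57, Rims1 and Rn45s respectively. Rn45s is listed at about 0 in HET 1 and HET 2, and Snord57 at about 0 in WT 2 and WT 3, which can be failed estimates. Apart from Scn4b and Rims1, the genes in this paragraph were chosen after their values were seen.

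**Figure D2:**
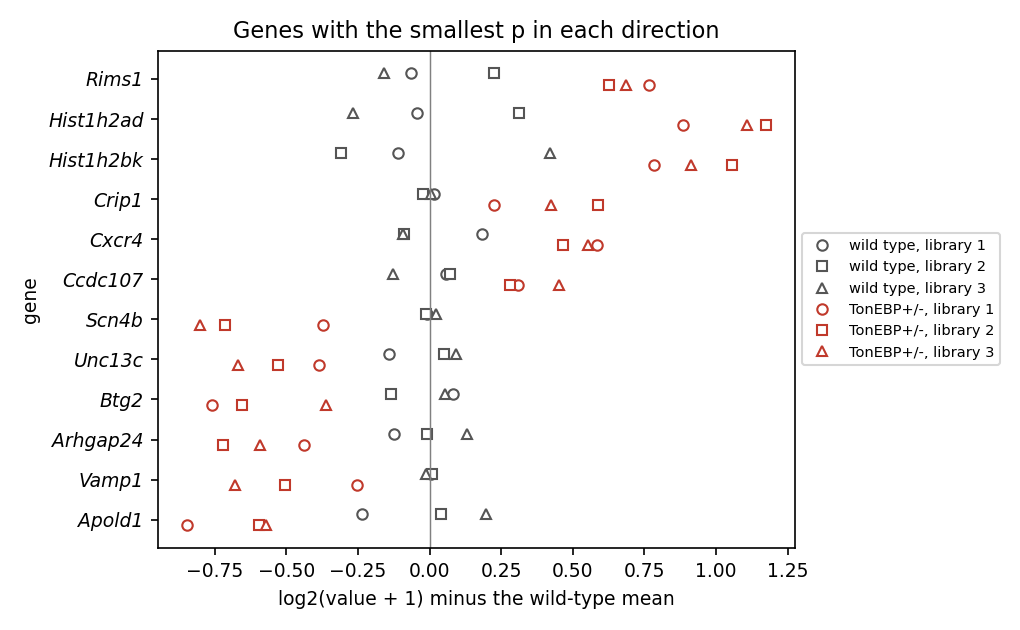
Deviation of each library from the wild-type mean, in log2(value + 1), for the 6 genes with the smallest p in each direction. Grey symbols are the 3 wild-type libraries and red symbols the 3 libraries labelled TonEBP+/-; the genotypes do not overlap in any of the 12 genes, and none passed the adjusted threshold (smallest adjusted p 0.383, Rims1 and Hist1h2ad).

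Gene lists fixed before the data were examined asked whether pathways, cell types or regions shifted as a set. Of 37 lists tested with camera at a preset correlation of 0.01, 5 passed an adjusted p of 0.05, and 0 of the 5 held with a correlation estimated from the data (smallest adjusted p = 0.915 with an estimated correlation). The directional test of fry also passed 0 lists (smallest adjusted p = 0.980). The number of lists past the threshold was 13 without WT 2, 9 without WT 3 or HET 2, 8 without HET 3 and 7 without HET 1. These counts, and the list values below with a library left out, another scaling or filter, or the thalamus covariate, are at the preset correlation. They were not computed with an estimated one. In each of the 5 lists 0 members passed, adjusted over all genes or adjusted over the list alone. Cholesterol synthesis genes were higher in 19 of 20 members (median log2 difference 0.09, adjusted p = 0.00071, and 0.915 with an estimated correlation). Among its members with the smallest p were Dhcr7 (0.29, SE 0.106), which encodes a late enzyme of the pathway, and Sqle (0.17, SE 0.0845), which encodes squalene epoxidase. The list did not pass without HET 2 (adjusted p = 0.128), the library with the highest list median (0.20 against 0.06 in HET 1 and 0.02 in HET 3). The wild-type medians were 0.03, 0.04 and -0.07, so that HET 3 lay within their range. Genes of disease-associated microglia and complement were higher in 20 of 22 members (median 0.05, adjusted p = 0.00782, and 0.962 with an estimated correlation), led by the lysozyme gene Lyz2 (0.37, SE 0.117), the complement gene C1qa (0.19, SE 0.0733) and the Fc receptor gene Fcgr3 (0.25, SE 0.103). HET 2 lay within the wild-type range of this list (-0.04), HET 1 and HET 3 above it (0.17 each). General microglia markers, which share 4 members with this list, C1qa among them, had medians of 0.17, -0.07 and 0.09 in HET 1 to HET 3 and did not pass with all 6 libraries (adjusted p = 0.160). No test set the list against the amount of microglia. The list did not pass without WT 1 (adjusted p = 0.332), HET 1 (0.206) or HET 3 (0.1), nor without the filter on low values (0.102).

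The other 3 lists that passed describe regions and cell types. Thalamus and habenula markers were lower in 12 of 15 members (median log2 difference -0.40, adjusted p = 0.00115, and 0.915 with an estimated correlation). The list median was 0.08 in HET 1, -0.62 in HET 2 and -0.73 in HET 3, against -0.08 to 0.06 in the wild-type libraries, so that HET 1 was not below the wild type. Tcf7l2, a thalamic transcription factor gene, was at 11.1 ± 2.54 FPKM in wild type and 6.32 ± 3.52 FPKM in libraries labelled TonEBP+/- (SD, n = 3 each), and Plekhg1 at 17.4 ± 1.26 against 12.9 ± 4.80 FPKM. The member with the smallest p, the tachykinin gene Tac2, lay in the other direction (log2 difference 0.35, SE 0.115). Without HET 3 the list did not pass (adjusted p = 0.1). Meningeal and fibroblast markers were higher in 13 of 13 members (median 0.20, adjusted p = 0.00135, and 0.915 with an estimated correlation), with Ogn (0.27, SE 0.154) and Fmod (0.44, SE 0.286), both small proteoglycan genes of the matrix, leading. The list median was -0.07 in HET 1, 0.57 in HET 2 and 0.21 in HET 3, and without HET 2 the adjusted p was 0.539. CA1 markers were higher in 7 of 9 members (median 0.09, adjusted p = 0.0306, and 0.915 with an estimated correlation), with Mpped1 (0.16, SE 0.0680) and Wfs1 (0.22, SE 0.151) among those with the smallest p. This list did not pass without WT 1 (adjusted p = 0.0916), WT 2 (0.113), HET 2 (0.0509) or HET 3 (0.157), nor with a stricter filter (0.101). With the mean of the thalamus markers as a covariate, an alternative chosen after seeing the data, the CA1 list (adjusted p = 0.462) and the meningeal list (0.795) did not pass either, whereas the cholesterol and microglial lists did.

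**Figure D3:**
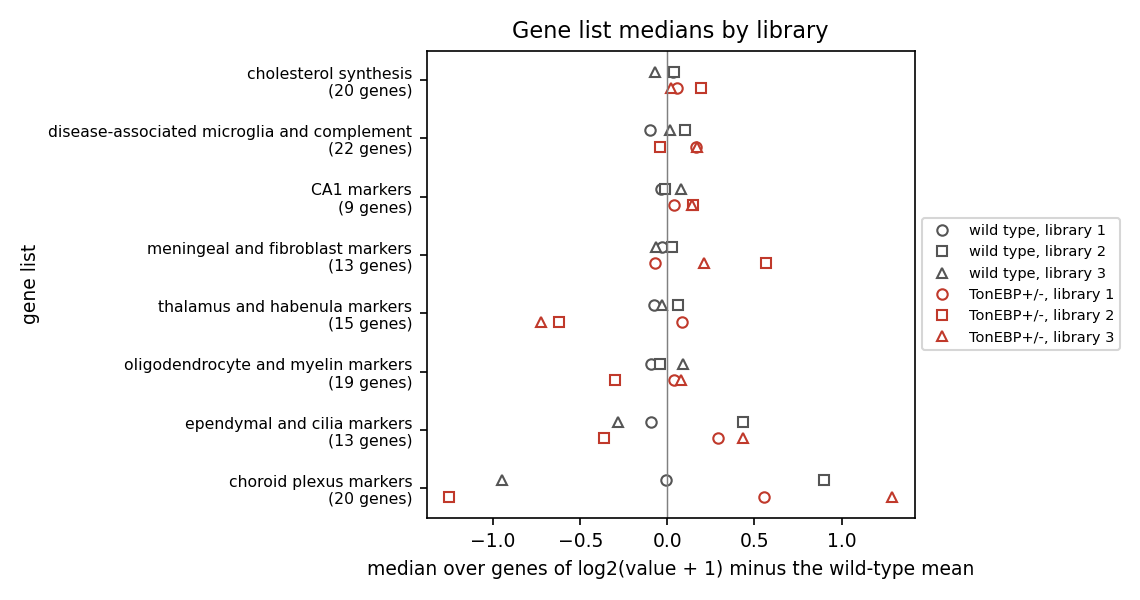
Median over the genes of each list of log2(value + 1) minus the wild-type mean, with one symbol per library (grey, wild type; red, labelled TonEBP+/-). Thalamus markers lay at -0.62 and -0.73 in HET 2 and HET 3 and at 0.08 in HET 1, and choroid plexus markers ranged from -1.25 (HET 2) to 1.29 (HET 3) with both genotypes spread across that range.

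Pathways tied to TonEBP were examined next. Osmoprotective targets of TonEBP, the transporters, enzymes and chaperones it activates in hypertonic medium, did not pass (10 of 18 higher, adjusted p = 0.854, median 0.02 and mean -0.00 of opposite sign). The members with the smallest p were the chaperone gene Hspa4l (-0.14, SE 0.0665) and S100a4 (-0.21, SE 0.103). NF-kB and inflammatory cytokine genes did not pass (8 of 11 higher, median 0.16, adjusted p = 0.160), with Il18 (0.22, SE 0.0986) and Nfkbiz (0.18, SE 0.123) leading, and 11 of the 32 genes of this list were expressed above the filter. Interferon-stimulated genes (12 of 23 higher, adjusted p = 0.567; Ifitm3, 0.25, SE 0.110, and Stat2, 0.22, SE 0.114) and the TRIM family (19 of 30 lower, adjusted p = 0.301; Trim36, -0.25, SE 0.110, and Trim13, -0.11, SE 0.0756) did not pass with all 6 libraries, and both passed without WT 2 (adjusted p = 0.0484 each). Peroxisome genes, a site where Trim37 acts, had an adjusted p of 0.942 (Pex2, -0.19, SE 0.143; Abcd3, -0.11, SE 0.0825), and autophagy and mTOR genes one of 0.854 (Atg10, -0.16, SE 0.0824; Tsc1, 0.10, SE 0.0817).

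The lists of chaperones, the respiratory chain, ribosomal proteins, senescence, glucocorticoid response, amyloid and tau, and the clock did not pass with all 6 libraries and the deposited scaling. Heat shock and chaperone genes were higher in 15 of 28 members (adjusted p = 0.160), with Xbp1 (0.24, SE 0.0834) and Creld2 (0.24, SE 0.0857) leading, and passed without WT 2 (0.0304) or HET 1 (0.0337). Respiratory chain genes were lower in 32 of 42 members (median -0.04, adjusted p = 0.113), with Cox5a (-0.12, SE 0.0726) and Atp5a1 (-0.11, SE 0.0756) leading, and cytosolic ribosomal protein genes were higher in 38 of 47 (adjusted p = 0.301; Rpl30, -0.45, SE 0.204, and Rps4x, -0.19, SE 0.137). The respiratory chain list passed with quantile normalization (adjusted p = 0.0375) and without WT 1 (0.00118), WT 3 (0.00699) or HET 3 (0.0215). The ribosomal list passed without WT 2 (adjusted p = 3.89e-08) or HET 2 (0.00102) and with the thalamus covariate (0.0342). The estimated correlation was 0.555 for the respiratory chain list and 0.784 for the ribosomal list. With it, neither passed on all libraries (adjusted p = 0.962 each). Senescence genes had an adjusted p of 0.610 (Plk2, 0.13, SE 0.0933; Phlda3, -0.14, SE 0.119). Glucocorticoid-induced genes had one of 0.854, where the test pointed up and the median of -0.01 down, with Dusp1 (-0.62, SE 0.172) and Pdk4 (0.22, SE 0.110) leading. Amyloid and tau genes had one of 0.942, with the gamma-secretase genes Aph1a (0.23, SE 0.0909) and Psenen (0.17, SE 0.0686) leading, and a median of -0.01 where the test pointed up. Psen2, a further gamma-secretase gene with a similar p, was lower (-0.27, SE 0.108); it was named after its value was seen. Clock genes had one of 0.942, with Hlf (-0.22, SE 0.0858) and Nr1d2 (-0.16, SE 0.0659) leading, and a median of 0.03 where the test pointed down.

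Among neuronal lists, immediate early genes did not pass as a set (15 of 29 lower, adjusted p = 0.301), and Btg2 alone passed when adjusted over the list alone. Among its other members, Dusp1 had a log2 difference of -0.62 (SE 0.172), Fos of -0.37 (SE 0.125) and Cyr61 of -0.38 (SE 0.132). The list passed as lower without HET 3 (adjusted p = 0.0032) and with the thalamus covariate (3.81e-06), both at the preset correlation of 0.01. Its estimated correlation was 0.393, and with it the adjusted p in camera on all 6 libraries was 0.962. In the glutamatergic synapse list (22 of 36 lower, adjusted p = 0.731), Rims1 passed when adjusted over the list alone, and Homer1, a gene for a postsynaptic scaffold protein, had a log2 difference of 0.23 (SE 0.110). Presynaptic vesicle genes were lower in 17 of 24 members (adjusted p = 0.609; Stx1a, 0.28, SE 0.114, and Cplx1, -0.17, SE 0.103). They passed without WT 2 (adjusted p = 0.0247) or HET 2 (0.00849), and the glutamatergic list passed without WT 2 (0.0247). CA3 and CA2 markers were lower in 9 of 10 members (median -0.07, adjusted p = 0.0756), and Pcp4, a calmodulin-binding protein gene, passed when adjusted over the list alone (204 ± 32.1 against 133 ± 26.9 FPKM, SD, n = 3 each; log2 difference -0.63). Its next member by p was Cacng5 (-0.25, SE 0.151). The CA3 and CA2 list passed without WT 2 (adjusted p = 0.0226) or HET 1 (0.00315), and did not pass with the thalamus covariate (0.900). Its list medians were 0.04, -0.08 and -0.01 in WT 1 to WT 3 and 0.02, -0.09 and -0.12 in HET 1 to HET 3. Excitatory neuron markers were higher in 11 of 14 (adjusted p = 0.1), while Slc17a6, the vesicular glutamate transporter gene that thalamic neurons express, had a log2 difference of -0.52 (SE 0.193) and Neurod2, a transcription factor gene, one of 0.20 (SE 0.0871). Inhibitory neuron markers had an adjusted p of 0.395 (8 of 15 lower), with Pvalb, the parvalbumin gene of fast-spiking interneurons, at 102 ± 23.7 against 73.3 ± 0.793 FPKM (SD, n = 3 each) and Gad2 at -0.22 (SE 0.111) on the log2 scale. Dentate gyrus granule markers had an adjusted p of 0.508 (Prox1, -0.16, SE 0.0958; C1ql2, -0.15, SE 0.0964). Cortex and amygdala markers had one of 0.512 (Lamp5, 0.26, SE 0.0862; Etv1, -0.16, SE 0.0686), and striatum markers one of 0.228 (Syndig1l, -0.30, SE 0.165; Penk, -0.14, SE 0.103). The excitatory list passed without WT 3 (adjusted p = 0.0334) or HET 3 (0.0408), the striatum list without WT 3 (0.0491) or HET 2 (0.0274), and the inhibitory list without HET 2 (0.0110). With the thalamus covariate the inhibitory (0.0246) and striatum (0.0375) lists passed.

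Markers of other cell types did not pass with all 6 libraries either, although some varied widely between libraries. Choroid plexus markers had an adjusted p of 0.560 with list medians of -0.01, 0.90 and -0.95 in WT 1 to WT 3 and 0.55, -1.25 and 1.29 in HET 1 to HET 3; Col8a1 (0.28, SE 0.570) and Prlr (0.33, SE 0.926) had its smallest p. Without WT 2 (adjusted p = 0.0108) or HET 2 (2.12e-11) this list passed as higher, and without HET 3 (0.0274) as lower, in libraries labelled TonEBP+/-. Those values are at the preset correlation of 0.01, whereas the correlation estimated for this list was 0.978. With the estimate its adjusted p in camera was 0.962 on all 6 libraries, so its genes are far from independent. Ependymal markers varied alongside, from -0.37 in HET 2 to 0.43 in WT 2 (adjusted p = 0.541), with Meig1 (-0.45, SE 0.226) and Ccdc153 (0.30, SE 0.265) leading. At the preset correlation the ependymal list passed as higher without WT 2 (0.0226) or HET 2 (2.59e-06). Its estimated correlation was 0.797, and with it the adjusted p on all 6 libraries was 0.962. Astrocyte markers had an adjusted p of 0.792, with a median of -0.01 against a mean of 0.01, and Vim (0.28, SE 0.0720) and Gfap (0.23, SE 0.119) leading, and passed as higher with the thalamus covariate (0.000277). Microglia markers were higher in 13 of 18 members (adjusted p = 0.160), with C1qa and Olfml3 (0.21, SE 0.109) leading. They passed without WT 3 (0.0334) or HET 2 (0.000318) and with the thalamus covariate (0.000277), at the preset correlation. The estimated correlation was 0.451 for astrocyte markers and 0.476 for microglia markers. With it, neither list passed in camera on all 6 libraries (adjusted p = 0.962 each). Oligodendrocyte and myelin markers were lower in 17 of 19 (median -0.05, adjusted p = 0.228; Mog, -0.17, SE 0.0878, and Gjc3, -0.14, SE 0.126), with a list median of -0.30 in HET 2, and passed without WT 1 (0.0224), HET 1 (0.0112) or HET 3 (0.0119). Oligodendrocyte precursor markers had an adjusted p of 0.970, with a median of 0.05 where the test pointed down, and Lhfpl3 (-0.24, SE 0.0846) and Cacng4 (-0.40, SE 0.166) leading. Endothelial and mural markers (adjusted p = 0.228; Slco1a4, 0.15, SE 0.0834, and Itm2a, 0.14, SE 0.0844) and blood cell markers (0.508; Alas2, 0.24, SE 0.129, and Bpgm, -0.10, SE 0.0879) did not pass, the former except without HET 3 (0.0124). Sex-linked transcripts had an adjusted p of 0.609 (Kdm5d, -0.08, SE 0.0863); the Y-linked gene Ddx3y was at 29.2 to 36.9 FPKM in all 6 libraries and Xist at no more than 0.0985 FPKM.

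Because the allele was back-crossed for 5 to 6 generations, genes near Nfat5 could carry DNA of another strain, and their expression was compared as well. Of 47 genes tested around Nfat5 on chromosome 8, 0 passed adjusted over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05, against 482 of the other 13075 genes (Fisher's exact test, two-sided, p = 0.692). These were Exosc6 (6.04 ± 0.376 against 7.29 ± 0.391 FPKM) and Nip7 (10.5 ± 0.614 against 12.1 ± 0.336 FPKM; SD, n = 3 each), both genes of RNA processing. The list did not pass (adjusted p = 0.855, median -0.00). Of 73 tested genes within 3 Mb in the annotation, 1 had an unadjusted p under 0.05 (Fisher's exact test, two-sided, p = 0.526).

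Libraries were similar within and between genotypes. The Pearson correlation across genes, which are not independent replicates, ranged from 0.973 to 0.983, with a median of 0.980 within and between genotypes alike, and no files held identical values. The first principal component took 28.5% of the variance and set HET 3 (-21.9) against HET 2 (21.3), with the wild-type libraries and HET 1 between them. The ribosomal RNA precursor Rn45s was at 8166, 12698 and 15465 FPKM in the wild-type libraries and 2556 FPKM in HET 3, and was listed at about 0 in HET 1 and HET 2, which can be a failed estimate.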

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

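The thalamus covariate was chosen after seeing the data; the other alternatives were planned, and those for counts did not apply. Nfat5 and Trim37 stayed lower in all 14 alternatives (log2 changes -0.20 to -0.06 and -0.07 to -0.03), and each of the 12 other named genes kept its direction in every alternative that kept it. The count of genes past the threshold was 0 in all alternatives except those that left out a library, where it ranged from 0 to 8 (8 without HET 1). Leaving out a library also moved the number of lists past the threshold from 5 to between 5 and 13. That of cell type, region and quality lists moved from 3 to between 3 and 7. At the preset correlation of 0.01, the adjusted p of the choroid plexus list moved to between 2.12e-11 and 0.958, with its direction turned without HET 3 (0.0274). The correlation estimated for that list was 0.978. With the thalamus covariate 8 lists passed, 5 of them of cell type, region or quality, and 2 of the 8 had passed without it; the thalamus list turned (adjusted p = 0.970) because its own mean was the covariate. With quantile normalization 6 lists passed, and with no filter or the stricter one 4. With an estimated correlation and with fry 0 lists passed. The median correlation between libraries was 0.929 with the stricter filter and 0.971 with the smaller pseudocount. The stricter filter is on the mean alone, so it kept Rnu6, which the main filter dropped. Rnu6 was listed at 2507040 FPKM in WT 1, 2173960 FPKM in WT 2 and about 0 in the other libraries. How far such rows lowered the correlation was not tested. With a replicate block, 0 genes and 5 lists passed, as without it, and 384 genes had an unadjusted p under 0.05. Libraries of the same number did not deviate together (correlations -0.21, -0.25 and -0.16 over genes). No pairing by number was seen, but correlations over all genes can miss a shared litter or day of small effect. Depth sets a floor of 0.0773 to 0.123 FPKM, the value of 1 fragment in 1 kb.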

Other observations

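The tests of genotype on thalamus markers, of RNAs without a tail and of the genes near Nfat5 at an unadjusted p were chosen after their result was seen. The further marker sets and the dividing-cell genes were chosen after the patterns, and before the values of their genes were seen. Replication-dependent histone genes, a family chosen after seeing the data, were higher in libraries labelled TonEBP+/- in 44 of 54 tested members (median log2 difference 0.17; 42 to 45 members with another scaling or pseudocount). With 0 members past the adjusted threshold, 12 had an unadjusted p under 0.05. The family was singled out because 2 of its members led the comparison, so no test of its shift is given. Per-library medians were -0.18, 0.15 and -0.00 in WT 1 to WT 3 and 0.23, 0.17 and 0.12 in HET 1 to HET 3, and without WT 1 the median difference was 0.08.

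Replication-dependent histone mRNAs typically carry no poly(A) tail and are made mainly in dividing cells, which gave a pair of candidate explanations. The 54 genes were taken by symbol, and whether this holds for each of them in the hippocampus was not tested. The comparison assumed that more dividing cells would raise their other genes by about as much, which was itself not tested. In 13 tested genes of division and DNA replication the median difference was -0.0366 (2 of 13 higher). It lay below that of the histone genes by more than 2 standard errors over genes, which are not independent replicates. Their per-library medians were -0.09, -0.00 and 0.05 in WT 1 to WT 3 and -0.09, -0.04 and -0.06 in HET 1 to HET 3. No rise was seen in these genes, but an error over genes cannot decide the question for mice. A difference in the recovery of RNAs without a tail stays open: 8 other such RNAs (Rmrp, Rpph1 and others) differed between genotypes by 0.0756 in their per-library medians with a standard error of 0.224, too wide to decide. Over members their median log2 difference was 0.139 (7 of 8 higher), near the 0.17 of the histone genes. In both sets WT 1 had the lowest median (-0.29, and -0.18 for the histone genes). An effect of genotype stays open as well and was not tested apart from these.

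Most members of the thalamus and habenula list were lower in HET 2 and HET 3. Tac2 and Nwd2 were higher in both than in every wild-type library. The list was not split by region, so nothing is shown for the habenula alone. The dissections of HET 2 and HET 3 may have held less thalamic tissue. In that case most markers should be lower in both than in each of the other libraries. In the list that showed the pattern 12 of 15 were, all but Tac2, Nwd2 and Cplx3. In a further set of thalamus markers outside that list, 7 of the 9 tested were, among them Ntng1 and Amotl1, and Cbln1 and Zic5 were not. This is consistent with less thalamic tissue, and would also follow from a lower expression of thalamic genes in these 2 mice. Whether genotype lowers these markers in every TonEBP+/- mouse cannot be told apart from this, since 2 of the 3 libraries labelled TonEBP+/- lay below every wild-type library. HET 1 (0.08) lay above all 3 wild-type libraries (-0.08 to 0.06), which goes against a lowering in every mouse but is a single library. With the thalamus covariate the log2 difference of Scn4b was -0.44 (SE 0.0973) in place of -0.63 (SE 0.112), and that of Vamp1 -0.31 (SE 0.0826) in place of -0.48 (SE 0.0987), so part of these differences may follow the thalamic content. Of the 12 genes with the smallest p, 8 came closer to 0 with the covariate and 4 moved away from it, among them Btg2 (-0.75 in place of -0.59), Apold1 (-0.79 in place of -0.67) and Rims1 (0.76 in place of 0.69).

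Choroid plexus markers differed most between libraries: Ttr, the transthyretin gene and the most abundant of them, ran from 87.4 FPKM in HET 2 to 3338 FPKM in HET 3, a 38.2-fold range. Different amounts of choroid plexus in the dissections would move the markers together; in the list that showed the pattern 17 of 20 had their highest value in HET 3 and their lowest in HET 2. In a further set of choroid plexus markers outside that list 7 of the 12 tested did, among them Trpm3 and Car12, which is consistent with that explanation. Both genotypes held libraries with high and with low list medians (-0.01, 0.90 and -0.95 in WT 1 to WT 3; 0.55, -1.25 and 1.29 in HET 1 to HET 3), and no biological explanation was tested.

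With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other 27, and the real split gave 5 gene lists, where the other splits gave 6 to 15. The split with 27 genes set WT 2, HET 1 and HET 3 against WT 1, WT 3 and HET 2. All 27 were higher in the former, and 4 of them were ependymal markers and 0 choroid plexus markers. The choroid plexus list medians were also higher in the former (0.55 to 1.29 against -1.25 to -0.01). Ribosomal protein genes (Rpl37, Rps14 and Rps28) and small RNAs (Scarna6, Scarna13 and Snora74a) were among the 27 too. List medians of ribosomal protein genes divided in the same way (0.09 to 0.18 against -0.10 to -0.08). So did medians of the 8 RNAs without a tail, Scarna6 among them (0.16 to 0.39 against -0.29 to -0.06). This split was picked as the one with the most genes, where the others gave 0 or 1. The ribosomal list and the 8 RNAs hold genes called in it, so their medians are no separate support. Whether it reflects a structure of the samples that does not follow genotype was not tested.

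Strain DNA kept around the disrupted allele could raise the share of genes near Nfat5 with a low p. The odds ratio was 1.16 (Fisher's exact test, p = 0.692), with 2 such genes, and 0.361 (p = 0.526) with 1 such gene in the set from the annotation, too few to decide.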
